A study of Mus musculus with 2 samples.

How the data were processed

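Lung DNA of 2 mouse samples, 1 control and 1 with Th17-mediated neutrophil-predominant asthma, was measured by immunoprecipitation of methylated DNA followed by hybridisation to 2-colour arrays. Per the labels, Cy5 (red) carried the immunoprecipitated DNA and Cy3 (green) the input of the same sample, without a dye swap. The labels do not say whether a sample is the DNA of 1 mouse or a pool. Groups were taken from the labels. Both arrays lay on 1 slide and were read in 1 scan, the control at array position 3 and the asthma sample at position 1, so that slide position and group cannot be told apart.

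Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 11.0.1.1 and its ChIP protocol on an array design with mm9 coordinates. Their spot and background intensity values are median pixel intensities per the file headers. The processed intensity values were background-subtracted and scaled by 1 linear dye factor per channel per the file headers (3.03 for the input and 2.95 for the IP in control, 4.76 and 3.37 in asthma), with no lowess step. The deposited log10 ratio of red over green was the same, to 4 decimals in nearly all probes, as that computed from the processed signals. The deposited error score of that ratio comes from the scanner software's error model, and the other deposited columns used were flags for background, outliers and saturation. The authors' series table holds log2 values of both arrays. Set against the scanner values, the table's direction is IP over input, its columns correlated with their own array's log2 ratio of spot medians at 0.936 in control and 0.930 in asthma, with slopes of 0.754 and 0.765, and their medians were 0.0467 and 0.0470. Neighbouring probes correlated at 0.716 and 0.695 in that table against 0.342 and 0.298 in the scanner values. How these values were scaled and centred, and whether they were smoothed along the chromosome, is not given in the sources used here. No column of per-sample values was left out.

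The value of a probe was log2 of the red over the green processed signal minus the median over all 174638 non-control probes of its array. That median was 0.117 in control and 0.081 in asthma. The 5827 control spots were left out. Probes were kept if their input was well above background on both arrays, which 17602 were not, and if they had no outlier mark in either channel, which 231 had on an array; 156818 probes (89.8%) remained. The IP was not required to be above background, so a ratio can rest on IP values near background. Saturated spots, 2 in control and 0 in asthma, were kept. Each channel was also centred on its own median for comparisons of a single channel.

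The design fixed before the data were examined summarised probes per gene. The probes carry mm9 coordinates without gene names here, and the gene table at hand is on assembly GRCm38.p6, so coordinates could not be matched and genes were not named. The 21 fixed gene and cell type marker lists, the comparison of gene classes and the genes singled out by name were not analysed here. In their place, chosen after seeing the data, probes with starts at most 1000 bp apart formed 22166 tiled regions, of which 21914 had at least 3 kept probes. The rest of the rule was as fixed: a region value is the mean over its probes, and a region is higher or lower in asthma if the arrays differ by at least 1.5-fold (0.585 on the log2 scale) and at least 80% of its probes have that sign. Runs are at least 4 neighbouring probes, each at most 500 bp from the next, that all pass the size rule in 1 direction. The regions named are the 10 largest differences in each direction among those with at least 4 probes, and the 3 largest runs in each direction, by the rule fixed beforehand; other regions named were chosen after their values were seen.

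No test was made and no p-value given, because each group has 1 array, and the number of arrays limits the precision of every difference. Spread over probes describes a region on these arrays and not animals. To describe what probe noise alone gives, probe differences were shuffled 100 times within 20 bins of mean ratio and 10 bins of signal, and were also drawn 100 times from the scanner software's error model around the median of their bin. Chromosomes were set against 10000 random sets of regions matched in 10 bins of mean ratio. Intervals are 95% bootstrap intervals from 1000 resamples of regions and leave out the difference between animals. The correlation of a region's difference between its odd- and even-numbered probes was 0.204, against 0.527 and 0.490 for the ratios of control and asthma. The classes of regions 2-fold and 4-fold from the array median and the matched counts of higher and lower regions per chromosome were chosen after seeing the data.

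The calling steps were tested on simulated data for this comparison, with 200 of the 21914 regions changed. At 1.5-fold, 46.0% of 50 changed regions were recovered, and at 2-fold, 3-fold and 4-fold 100.0% of 50 each, with 0 in the wrong direction. The change was added as a constant to shuffled probe differences of the ratio, so these shares follow largely from the size rule. An IP near background and the noise of each channel were not simulated. The result checks the calling steps and does not show that a methylation change of such a size would be found.

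Alternatives fixed before the data were examined were no centring, loess within each array (span 0.3), quantile normalization between arrays, normexp background correction with an offset of 50, the authors' series table, no background filter, a filter on both channels, the median over probes, at least 5 probes, removal of the trend on signal, a 2-fold rule, no rule on probe signs, and runs of at least 3 or 6 probes. The files used here hold no mean spot signals, so normexp was run on spot medians. Added after seeing the data were a gap of 500 bp between probes, removal of 2 slide areas with a shifted IP signal, each channel alone, and removal of X and Y. For the 11 called regions with spots in those areas, the number of lost calls, 7, was looked at first, and the size of the difference was then used instead, because 5 of the 7 ended just under the size rule. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.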

Results

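Methylated DNA from mouse lung was profiled on tiling arrays in 2 samples, 1 from control mice that received saline and 1 from mice with Th17-mediated, neutrophil-predominant asthma. The asthma model was set up with 100 µg of house dust mite, a common aeroallergen, 100 µg of ovalbumin, an egg-white protein used as a model allergen, and 15 µg of lipopolysaccharide, a component of the bacterial outer membrane that activates innate immune cells. Th17 cells are helper T cells that secrete interleukin-17 and promote the recruitment of neutrophils. In each sample, DNA enriched by immunoprecipitation of methylated DNA (IP) was labelled with Cy5 and the unenriched input of the same lung DNA with Cy3, and both were hybridised to 1 array. The log2 IP/input ratio therefore rises with the methylation of the DNA around a probe, and with the number of methylated CpG sites there. Each array held 174638 probes of 45 to 60 bases on 21 chromosomes. The median spot signal of the input was 235 over a background of 23 in control and 160.5 over 25 in asthma, and that of the IP was 206 over 12 and 174 over 11. Input signals were well above background for 95.7% of probes in control and 90.1% in asthma, and IP signals for 79.7% and 78.8%. With 1 array per group, no difference could be set against the spread between animals or arrays, and no p-value was computed. Every ± below is an SD over the probes of a region. Beside a ratio it is the SD of the probe ratios on that array, and beside a difference that of the asthma minus control probe differences. Probes were summarised over 21914 tiled regions, of a median 7 probes and 1612 bp, which are named by their mm9 coordinates because the probes were not tied to genes here.

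The first question was how far the profile of IP/input ratios was shared by both arrays. Most regions kept their place: the region ratios of the arrays correlated at a Pearson r of 0.978 (95% bootstrap interval over regions, 0.978 to 0.979) and a Spearman rho of 0.972, and 71.2% of regions differed by at most 0.2 on the log2 scale. A ratio at least 2-fold below the array median was found for 4929 regions in control and 4632 in asthma, of which 4261 were shared, and a ratio at least 4-fold below it for 1497 and 1349, of which 1237 were shared. At the enriched end, 342 regions lay at least 2-fold above the median in control against 158 in asthma, with 138 in both. This gap may reflect a small shift at a fixed cut, which was not tested. In the decile of probes with the highest mean ratio, the median difference was -0.15, with the input higher in asthma by 0.25 and the IP by 0.081. The counts of these classes were not repeated under other scalings. The spread of probe ratios was also slightly wider in control (SD 1.68) than in asthma (SD 1.62). These correlations are across regions, which are not independent replicates. The ratio also followed probe length on both arrays. Its median was 0.65 in control and 0.58 in asthma for probes of 45 bases, and -2.59 on each array for those of 58 to 60 bases. How much of the correlation comes from the probes, which both arrays share, and how much from methylation was not tested.

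**Figure D1:**
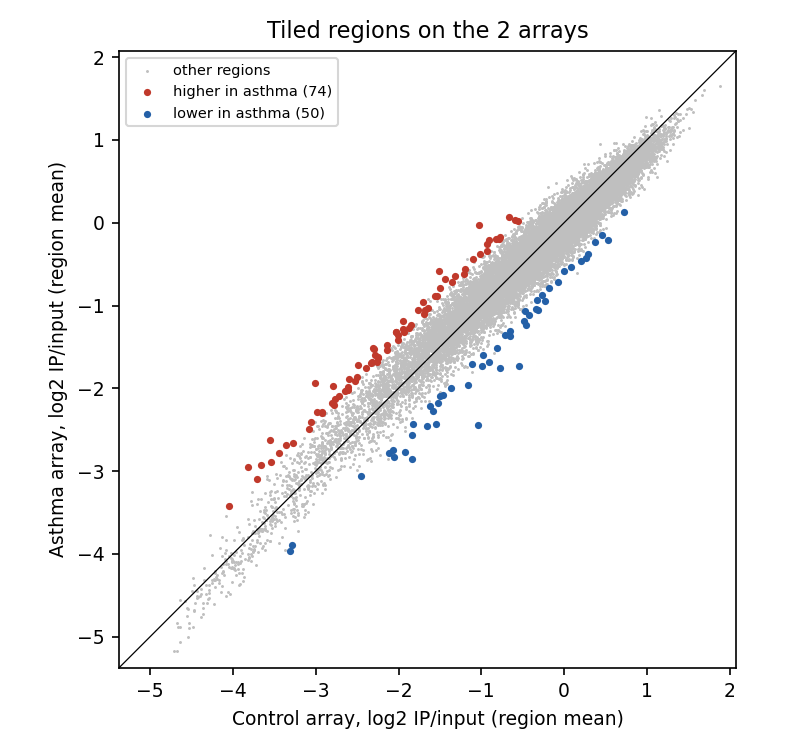
Each point is a tiled region, with its mean log2 IP/input on the control array (x axis) and on the asthma array (y axis), and the line marks equal values. The 74 regions higher and 50 lower in asthma past the 1.5-fold rule are coloured, and the remaining regions (grey) lie along the line (Pearson r 0.978).

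The main comparison asked which regions differed in methylation between asthma and control lung. The IP/input ratio was at least 1.5-fold higher in asthma in 74 regions and at least 1.5-fold lower in 50, together 0.57% of those tested, with at least 80% of the probes of each region pointing the same way. The region furthest down was on chromosome X, from 58438238 to 58439576, with a log2 IP/input of -1.04 ± 0.53 in control and -2.44 ± 1.33 in asthma over 6 probes, a 2.64-fold lower ratio. The IP was well above background in all 6 of these probes on both arrays. At a 2-fold rule 3 lower regions passed, and 1 higher region, on chromosome 17 from 53985066 to 53986536, whose IP was well above background in only 2 of 7 probes in control and 3 in asthma, so that its size is not given. At least 3 probes had an IP well above background on both arrays in 45 of the 74 higher and 39 of the 50 lower regions.

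Regions higher in asthma were mostly depleted on both arrays. Their median log2 IP/input was -2.19 in control and -1.52 in asthma, and 71 of the 74 lay below the array median on both. Of the 10 largest listed differences, 3 are given without a size or place, since under 3 of their probes had an IP well above background on both arrays: that region of chromosome 17, chromosome 9 from 92203010 to 92204608 (1 of 5 probes) and chromosome 17 from 38690682 to 38691507 (2 of 4). Of the other 7, the furthest up were on chromosome 15 from 82979270 to 82980435 (difference 1.00 ± 0.65, 4 probes), chromosome 2 from 104398056 to 104399983 (0.92 ± 0.79, 4 probes) and chromosome 10 from 97027453 to 97028340 (0.81 ± 0.38, 5 probes). A group of 4 smaller differences between 0.75 and 0.77 followed, on chromosome 13 from 23643360 to 23644643, chromosome 7 from 116073217 to 116074597, chromosome 1 from 163324773 to 163326052 and chromosome 5 from 120030073 to 120031365. All probes pointed up in each of these 7 regions except that on chromosome 13, where 4 of 5 did. In the authors' table the chromosome 1 region differed by 0.42. The chromosome 15 region fell to 0.49 without the background filter, those on chromosomes 2 and 13 to 0.55 and 0.47 with a filter on both channels, that on chromosome 1 to 0.49 after normexp, and the median over probes gave 0.45 on chromosome 5 and 1.18 on chromosome 13.

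Regions lower in asthma started from a higher level, with a median log2 IP/input of -0.80 in control and -1.64 in asthma. In 8 of the 50 the ratio lay above the array median in control and below it in asthma. Chromosome X held the 3 lowest. The second was the region from 70327361 to 70328021 (difference -1.18 ± 0.40, 4 probes) and the third that from 70458404 to 70460193 (-1.03 ± 0.79, 6 probes), with a further X region from 70487983 to 70489572 (-0.79 ± 0.96, 6 probes) in the same neighbourhood. The lowest on an autosome was on chromosome 13 from 59832627 to 59835003 (-0.98 ± 0.94, 9 probes), followed by chromosome 15 from 39793008 to 39794511 (-0.85 ± 0.62, 8 probes) and chromosome 14 from 105513809 to 105515134 (-0.80 ± 0.21, 4 probes). The regions on chromosome 7 from 29235716 to 29237455 and chromosome 17 from 47766353 to 47768055 differed by -0.78 each. That on chromosome 1 from 30919602 to 30920989 is given without a size, since its IP was well above background in 3 of 6 probes in control and 2 in asthma. After normexp the X region from 70458404 had -0.51, and those on chromosomes 15, 14, 7 and 17 had -0.36, -0.42, -0.38 and -0.51. The chromosome 13 region had -0.50 with the median over probes, the chromosome 14 region -0.49 without the background filter, and those on chromosomes 15 and 7 -0.36 and -0.33 with a filter on both channels.

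When the probe differences were shuffled 100 times among probes of similar ratio and signal, a mean of 76.5 regions and at most 98 passed the same rule, against the 124 observed. The mean of the shuffles was 61.7% of the observed number. The scanner software's own error model gave a mean of 86.4 and at most 106, with up to 67 higher and 54 lower regions, so that the 50 lower regions were within its range. The balance of directions depended on the scaling: 59.7% of the regions were higher in asthma after median centring, against 50 higher and 73 lower without centring, 29 and 88 after quantile normalization, 140 and 225 after loess and 85 and 4 after normexp background correction.

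The ratio of a region can differ through either of its channels, so each was compared between the arrays on its own. In the higher regions the input was lower in asthma by a median log2 difference of -0.61, while the IP differed by 0.011. In the lower regions the input was higher by 0.62 and the IP differed by -0.085, over all kept probes, those with an IP near background included. The chromosome 17 region from 53985066 to 53986536 had an input difference of -1.07, with few probes to compare in the IP, and the X region from 58438238 to 58439576 had 1.16 and -0.26. A single region, on chromosome 15 from 82979270 to 82980435, passed the size rule in the IP in the direction of its ratio, with 0.83 in the IP and -0.14 in the input. That IP value rested on 1 of its 4 probes, at 3.20, and the mean of the other probes was 0.041. Over all tested regions the difference in the ratio correlated at -0.817 with the difference in the input and at 0.075 with that in the IP, and the SD was 0.229 for the input and 0.133 for the IP. With the IP channel alone, 3 regions were higher and 41 lower in asthma, and 0 of them were among the regions of the ratio with the same direction.

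**Figure D2:**
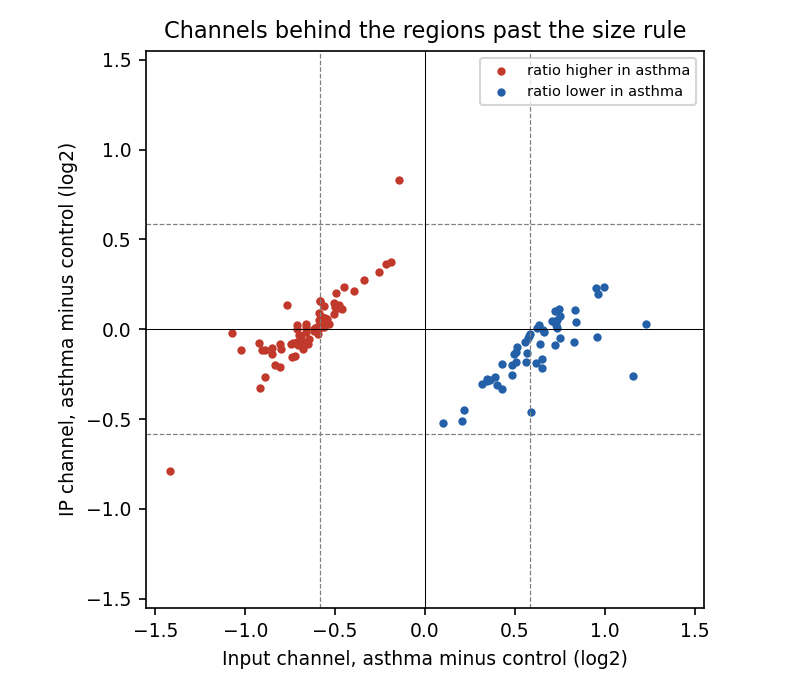
Each point is 1 of the 124 regions past the 1.5-fold rule, with its asthma minus control difference in the input channel (x axis) and in the IP channel (y axis), both log2, and dashed lines mark 1.5-fold. Points with a higher ratio lie on the left with lower input and those with a lower ratio on the right with higher input, and a single point passes the dashed line of the IP in the direction of its ratio.

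Shorter stretches inside the tiled regions were examined as runs of at least 4 neighbouring probes that all differed by 1.5-fold or more in the same direction. There were 19 runs higher and 24 lower in asthma. The lowest were on chromosome 13 from 59834287 to 59835003 (log2 IP/input -1.07 in control and -2.99 in asthma, difference -1.92 ± 0.17, 4 probes, 3.78-fold lower), chromosome X from 58438238 to 58439113 (-1.72 ± 0.18, 5 probes) and chromosome X from 70459326 to 70459983 (-1.47 ± 0.50, 4 probes). The highest were on chromosome 6 from 114346645 to 114347375 (1.09 ± 0.33, 4 probes) and chromosome 16 from 32912886 to 32913615 (1.08 ± 0.44, 4 probes), and the third named by rule was the chromosome 17 region above, given without a size. The longest run, singled out after its values were seen, covered 10 probes of chromosome 2 from 174172455 to 174174355 and went from -1.47 in control to -2.88 in asthma (difference -1.42 ± 0.41). Shuffled probes gave a mean of 13.2 runs and at most 24, against the 43 observed. The input passed the size rule in 40 of the 43 runs and the IP in 0, and without centring there were 12 higher and 39 lower runs.

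**Figure D3:**
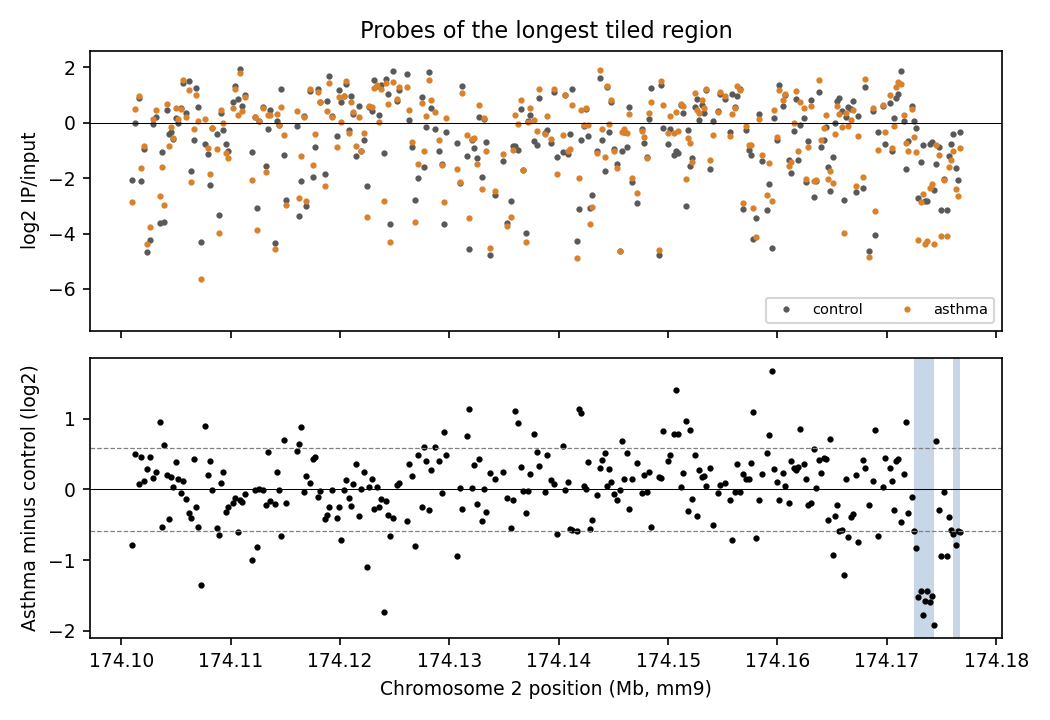
Each point is a probe of the tiled region on chromosome 2 from 174100927 to 174176708 (294 probes), with log2 IP/input of control and asthma above and the asthma minus control difference below, and dashed lines at 1.5-fold. The shaded spans are the 2 runs lower in asthma, of 10 probes (difference -1.42) and 4 probes (-0.65), at the distal end, while the region as a whole had -0.67 in control and -0.68 in asthma.

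Differences were then compared between chromosomes, including the sex chromosomes. Chromosome X carried 13 of the 50 lower regions (26.0%) but 3 of the 74 higher ones, although it held 932 of the 21914 regions. In 10000 random sets of regions matched to X in their mean ratio, the mean number of lower regions was 3.09 and the highest 10. These sets drew regions singly, whereas some of the lower regions on X lie close together or are alike, and may not be independent. The 13 regions had a median log2 IP/input of -1.58 in control and -2.44 in asthma, and X also carried 7 of the 24 lower runs. Over all X regions the median difference was -0.037, against 0.0067 in matched sets and below all 10000 of them. Chromosome 7 also lay below all of its own (-0.031 against -0.0087), and chromosome 15 (-0.042 against -0.025), chromosome 10 (0.0085 against -0.015) and chromosome 16 (0.0052 against -0.012) lay outside the central 95% of theirs. X lay below the autosomes under each alternative that gave a value for it. On chromosome 4, 9 regions were lower and 1 higher, against means of 2.96 and 4.40 in matched sets, and on chromosome 7 10 were lower and 12 higher, against 5.95 and 10.4. Autosomal medians ranged from -0.042 on chromosome 15 to 0.0085 on chromosome 10. The number of lower X regions moved with the processing, to 3 of 4 after normexp and 25 of 225 after loess.

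**Figure D4:**
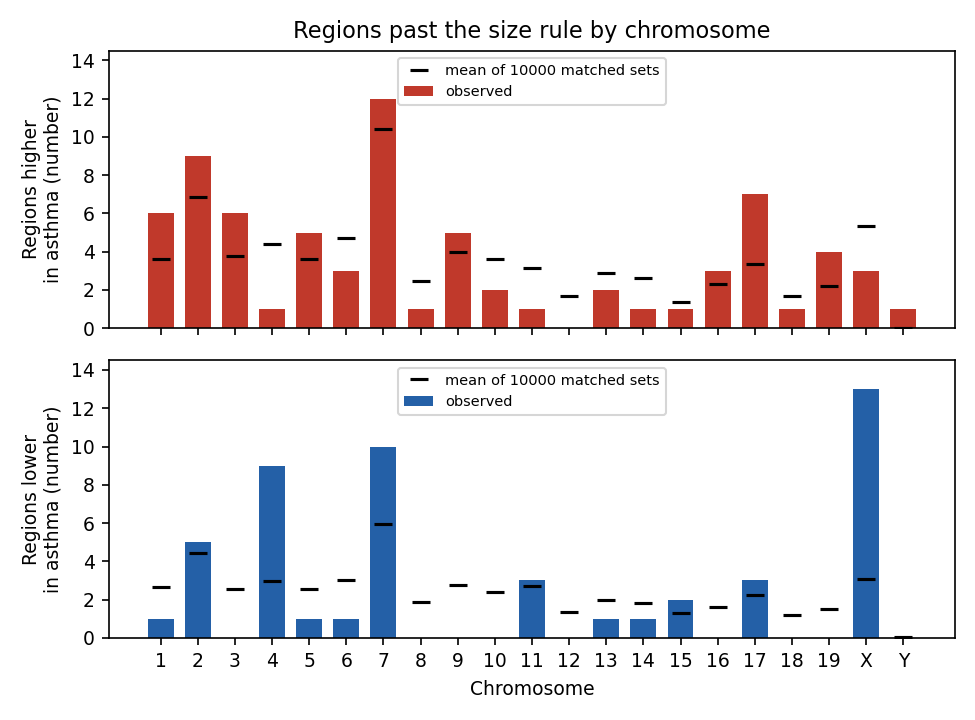
Bars give the number of regions higher (top) and lower (bottom) in asthma past the 1.5-fold rule on each chromosome, and short lines the mean number in 10000 sets of regions matched on mean log2 IP/input. Chromosome X stands out in the lower panel with 13 regions against a matched mean of 3.09, followed by chromosome 7 with 10 against 5.95 and chromosome 4 with 9 against 2.96.

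Chromosome Y was covered by 13 regions. Their median difference in the ratio was -0.038, the value of matched sets, and its sign relative to the autosomes changed with the processing. The 1 Y region past the size rule ran from 2155861 to 2157032 and was higher in asthma, at -0.66 ± 2.01 in control and 0.075 ± 1.75 in asthma (5 probes). Both channels of Y were lower in asthma, by a median log2 difference of -0.17 in the input and -0.085 in the IP, where matched sets had 0.081 and 0.028. The lowest inputs were those of the regions starting at 2155861, 2187455 and 2386220, which are alike in length and ratio and may not be independent. In some other Y regions the input was higher in asthma, such as that starting at 394826 (0.20).

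The arrays also differed along the range of signal, as a trend over all probes. In the decile of probes with the weakest signal the ratio was higher in asthma (median difference 0.11, log2 IP/input -3.21 in control and -3.06 in asthma), and in the strongest decile it was lower (-0.099, 0.66 and 0.59). The strongest minus the weakest decile gave -0.21, which turned to 0.044 in the authors' table and shrank to -0.016 after quantile normalization. By probe length, the 81956 probes of 45 bases had a median difference of -0.084, the 11892 probes of 54 to 57 bases one of 0.073, and the 20997 longest probes, of 58 to 60 bases, one of 0.027. Removing the trend on signal left 45 higher and 52 lower regions, of which 40 and 40 were also called before.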

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

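The removal of the shifted slide areas was added after seeing the data, with its prediction written before its result was known, and all other tests in this part were chosen after the result was seen.

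The input channel, which measures DNA amount and not methylation, was compared between the arrays in 879 blocks of 2 Mb with at least 8 regions, after adjustment for probe length and mean ratio. In 3 blocks the adjusted input differed between the arrays by at least 0.25 on the log2 scale, where the SD over blocks was 0.058. These were chromosome X from 10 to 12 Mb (-0.34), chromosome 7 from 10 to 12 Mb (-0.26) and chromosome X from 58 to 60 Mb (0.36). In the chromosome 7 block the input was lower in asthma in 21 of 23 regions and the IP difference was -0.16. The X block from 58 to 60 Mb held 2 regions lower in asthma, with an IP difference of -0.039.

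In the block of chromosome X from 10 to 12 Mb, both the input and the IP were lower in asthma, in 13 of 15 regions each, by -0.34 and -0.25. A difference in copy number between the DNA samples, which lowers both channels alike, may be a part of it: the IP minus the input difference was 0.091, within its spread of 0.170 (2 standard errors), but 18 of the 879 blocks, that of chromosome 7 from 10 to 12 Mb among them, met the same criterion. The IP does not set the block apart, since the 14 other blocks with at least as strong an input in control had a median IP difference of -0.16 and a lowest of -0.30. The input does differ from theirs, with a median of -0.019 in those 14 blocks. Adjustment for probe length and mean ratio moved the input difference of the block from -0.43 to -0.34, so these traits accounted for a small part of it. Other features of probe composition stay open, and the block was chosen on its adjusted input. Whether the lungs differed in this way because of asthma or between individual mice was not tested.

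The regions past the size rule differed mainly in the input, by a median of -0.61 when signed by the direction of the ratio, against 0.026 in the IP. Over all regions, the difference in the ratio correlated at -0.817 with that in the input and at 0.075 with that in the IP. These correlations follow in part from the ratio being built from both channels. For a change in the amount of methylated DNA recovered, the cut was set by convention at 1/2 of the median ratio difference. In the 90 regions with at least 3 probes above background in the IP on the array of the higher ratio, that cut was an IP difference of 0.32. Their median IP difference in the direction of the ratio was 0.058 (95% bootstrap interval 0.031 to 0.097), which argues against a change in the IP alone as the main source for these. The differences in the 2 channels correlated at 0.514 over all regions. A part shared by both channels, which the ratio takes out, could mask an IP change, so a change in recovery is not excluded. It also stays open for the other 34, where an IP near background can hardly move. Noise of single spots, shuffled or drawn from the scanner error model, gave at most 67 higher regions against 74, which argues against it as the whole source of these, and at most 18 higher runs against 19 and 12 lower runs against 24, which argues against it as the whole source of the runs, while the lower regions, 50 against at most 42 shuffled but 54 in the error model, leave it open for that set and for many single regions. Of the 124 regions, 113 held no spot of the shifted slide areas, which argues against those areas for these. The areas were chosen by their IP signal, so an area with a shifted input is not covered by this check. Such a spot lay in 10 of the 50 lower and 1 of the 74 higher regions, against 1422 of all 21914 tested, so these areas were over-represented among the lower regions. In the 11 regions that held one, the median difference, signed by the call, went from 0.65 to 0.56 without those spots (95% bootstrap interval 0.54 to 0.60). It stayed above 1/2 of its value (0.32). Few of the probes of each region were such spots, so a fall that large could hardly occur, and the spots stay open as a source for these regions. Without them, 7 lower regions fell below the size rule, 2 of them far, to -0.26 and -0.39. The total of 122 without these spots (79 higher and 43 lower) decides nothing, since the spots touched too few regions. Labelling or hybridisation of the input and a difference in the lung DNA stay open, since slide position and group cannot be told apart, and choosing regions by the ratio also favours the channel with the wider spread.

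Lower regions were over-represented on chromosome X, at 13 of 50. The lower ratios of X, where differences are noisier, gave at most 10 lower regions in 10000 matched sets, which argues against them as the whole source if the lower regions on X are independent. For less methylated DNA from X in asthma, the cut by the same convention was an IP fall of 0.36, 1/2 of the median fall in the ratio. Over the 11 regions with at least 3 probes above background in the control IP the median was 0.21 (95% bootstrap interval 0.059 to 0.41), so this source stays open. The upper end of that interval equals the IP fall of the region starting at 157204657. That region held a spot of the slide areas with a shifted IP, and without it its ratio difference (-0.56) no longer passed the size rule. The largest of these falls came from the regions starting at 131906828 and 131967379, which are alike in length and ratio and may not be independent. For a different mix of male and female DNA, the cut was a shift in the input of X as a whole of 0.29, 1/2 of the median input difference of the lower regions on X. The input of X lay 0.043 above matched sets. Y lay below its own matched sets in the input (-0.25) and the IP (-0.11), so a small difference in the mix stays open. The input of Y rests in part on regions that are alike in length and ratio and may not be independent. A local difference in input, technical or from the asthma lung, may remain, and the count itself moved from 3 after normexp to 25 after loess.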

How the results depend on the processing

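The 500 bp gap, the removal of slide areas, each channel alone and the removal of X and Y were chosen after seeing the data. Each group had 1 array, so leaving out an array was not an option. No paired analysis was possible because each group held 1 array. The alternatives planned for gene lists, gene classes and named genes were not run, since probes were not tied to genes. Where a value below moved, the cause was not tested.

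The 26 regions and runs named by rule kept their direction in all 318 values under the alternatives other than single channels, 9 of which moved by more than the spread over probes. Not all had a value under each: with a filter on both channels 21 had one and 5 had none, among them the chromosome 17 region from 53985066, with at least 5 probes 17 had one, and without X and Y 20 had one. These regions and runs were chosen as the largest differences on the same arrays, and some of the runs lie inside the named regions. Several alternatives, such as the 500 bp gap or the removal of X and Y, left their values unchanged. The kept direction therefore says little about stability. The median difference of X relative to the autosomes was -0.023 and ranged from -0.039 after quantile normalization to -0.0047 after normexp. The numbers of regions were less stable. Against 74 higher and 50 lower, there were 50 and 73 without centring (40.7% higher against 59.7%), 140 and 225 with loess, 29 and 88 with quantile normalization, 85 and 4 with normexp, 15 and 9 in the authors' table, 147 and 33 without the background filter, 45 and 52 without the trend on signal, 1 and 3 at 2-fold, 3 and 41 in the IP alone and 169 and 93 in the input alone with its sign turned. Shared with the main result were 56 and 47 regions under loess, 28 and 44 under quantile normalization, 27 and 4 under normexp, 12 and 9 in the authors' table, 26 and 24 with a filter on both channels, 0 and 0 in the IP alone and 40 and 24 in the input alone.

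Runs were 19 higher and 24 lower, and 12 and 39 without centring, 32 and 72 with loess, 14 and 43 with quantile normalization, 15 and 5 with normexp, 17 and 12 in the authors' table, 77 and 26 without the background filter, 10 and 15 with a filter on both channels, 179 and 133 with at least 3 probes, 1 and 2 with at least 6, 0 and 1 in the IP alone and 44 and 39 in the input alone. Lower regions on X, 13 in the main result, numbered 25 with loess, 20 with quantile normalization, 3 with normexp, 6 in the authors' table, 7 without the background filter, 8 with a filter on both channels, 3 at 2-fold, 2 in the IP alone and 6 in the input alone.

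The median difference of Y relative to the autosomes was -0.024 (95% bootstrap interval -0.075 to 0.31) and turned to 0.083 with loess, 0.070 with normexp, 0.016 in the authors' table, 0.037 without the background filter, 0.028 with the median over probes and 0.0056 with at least 5 probes. The strongest minus the weakest signal decile, -0.21, turned to 0.024 with loess, 0.044 in the authors' table and 0.088 without the trend, and moved to -0.016 with quantile normalization, -0.11 with normexp, -0.45 without the background filter and -0.16 with a filter on both channels; loess and trend removal take this trend out by construction.

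The correlation between arrays, 0.978, moved to 0.954 with loess, 0.974 with normexp, 0.982 in the authors' table, 0.975 without the background filter, 0.966 with a filter on both channels and 0.959 with the median over probes. The correlation between odd and even probes, 0.204, moved to 0.163 with quantile normalization, 0.302 with normexp, 0.711 in the authors' table, 0.240 without the background filter, 0.182 with a filter on both channels and 0.174 without the trend. The share of probes well above background was lower in the IP, at 79.7% in control and 78.8% in asthma, against 95.7% and 90.1% in the input, the channel the filter used.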

Other observations

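The regions below were picked after their values were seen, and no test was run on them.

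Besides its short regions, the array tiled 9 long stretches with at least 50 probes, and on each the probe profiles of control and asthma followed each other, with correlations over probes from 0.921 to 0.973. The stretch on chromosome 4 from 116177063 to 116207684 was the most shifted, with log2 IP/input -1.33 ± 1.54 (SD) in control and -1.07 ± 1.49 in asthma over 77 probes, a difference of 0.26 ± 0.49, of which the input made -0.30 and the IP -0.053. On chromosome 7 from 149759043 to 149806238 the ratio was lower in asthma, at -0.0020 in control and -0.17 in asthma over 199 probes (difference -0.17 ± 0.47). Stretches on chromosome 13 from 23766152 to 23784097 and from 23822417 to 23838932 differed by 0.098 ± 0.60 and 0.14 ± 0.54, and that on chromosome 11 from 103557750 to 103586053 by 0.0006 ± 0.45 over 104 probes. Of neighbouring stretches of chromosome X, that from 100625556 to 100651124 differed by 0.13 ± 0.49 and held 1 run higher in asthma. The stretch from 100652509 to 100680021 differed by -0.063 ± 0.55, close to its standard error over probes of 0.059, and held 1 lower run. The IP was lower in asthma in both (-0.044 and -0.079), and the input differed by -0.16 and 0.0041.

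On chromosome X, the regions from 131906828 to 131908203 and from 131967379 to 131968754, both 1376 bp with 7 probes, were lower in asthma, with the IP well above background in 4 of 7 probes in control and 2 in asthma in each, so that no size is given. On chromosome Y, the regions starting at 2155861, 2187455 and 2386220, of 1172, 1171 and 1172 bp, had differences of 0.74 ± 0.32, 0.51 ± 0.25 and 0.54 ± 0.32 over 5 probes each, of which the first alone passed the size rule, input differences of -0.71, -0.44 and -0.49, and IP differences of 0.0037, 0.049 and 0.028. Being alike in length and ratio, these Y regions may not be independent.

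In the block of chromosome 7 from 22 to 24 Mb, 48 regions had a mean log2 IP/input of -3.94 in control and -4.05 in asthma, and both channels were lower in asthma, by -0.45 in the IP and -0.33 in the input. After adjustment for probe length and mean ratio these were -0.30 and -0.062. Some of these regions, such as those starting at 22145885 and 22628861, are alike in probe number and channel differences. They may not be independent, so the number of regions may overstate the evidence.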
